A study of Drosophila melanogaster with 12 samples.

How the data were processed

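RNA abundance was measured in whole Drosophila melanogaster females with Affymetrix Drosophila Genome 2.0 arrays, 4 for each of 3 groups: virgin, single mated and double mated. Every array held RNA of its own pool of 8 flies, and the 4 pools of a group came from separate extractions. The deposited values are log2 RMA summaries, 1 per probe set and array, according to the submitters' processing notes, which name RMA and the affy package. RMA includes quantile normalization, and the medians of the 12 arrays ran from 5.97 to 6.07 on the log2 scale. Array values carry no read depth, and the number of arrays limits the precision.

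The deposited table held 18952 probe sets. The 183 Affymetrix control probe sets were left out, and the other 18769 were tested without a filter on signal. Of these, 13646 had 1 gene symbol in the platform annotation and stood for 11981 genes, and 4721 had none or were not listed. A further 402 probe sets with several symbols were kept in the counts of probe sets but not used for a named gene or a gene list. A gene with several probe sets was represented by the one with the highest mean over the 12 arrays.

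Group means were fitted to all 12 arrays together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). The labels give no hybridization batches. The comparisons were mated (the mean of the single and double mated groups) against virgin, single mated against virgin, double mated against virgin, and double mated against single mated, with a moderated F test over the 3 groups. A probe set was called changed at a Benjamini-Hochberg adjusted p under 0.05. The same fit was tested on simulated data, in which 200 of 18769 probe sets were shifted. For mated against virgin it recovered 16.5% of shifts of 0.25 on the log2 scale, 89.0% of shifts of 0.5 and 99.5% of shifts of 1. For double against single mated the shares were 1.5%, 81.0% and 98.0%. These shares hold for so few shifted probe sets with independent noise. They do not give the sensitivity in the data, where 4594 probe sets were called for mated against virgin and the adjusted threshold is therefore less strict.

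Before the data were examined, 30 gene lists were fixed from general knowledge of the fly. They covered antimicrobial peptides, peptidoglycan recognition and the Imd pathway, the Toll pathway, melanization, Turandot peptides with JAK/STAT, hemocyte markers, midgut serine proteases, and gut carbohydrases with lipase and lysozymes. Reproductive lists were eggshell proteins, yolk and lipid transport, germline and maternal genes, DNA replication, secreted products of the sperm storage glands, juvenile hormone and ecdysone, and postmating neural and oviduct genes. Metabolic and tissue lists were insulin and nutrient genes, fat body storage and lipogenesis, male accessory gland, testis and sperm, muscle, photoreceptor, neuron and circadian clock. The remaining lists were heat shock, ribosome biogenesis, odorant-binding proteins, cytochromes P450, glutathione and UDP transferases, ribosomal proteins and the proteasome. Each list was tested with limma camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists of a comparison, and again with the correlation estimated from the data. Members past the threshold were counted over all probe sets and adjusted over the list alone.

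Genes are named by a rule that was also fixed before the data were examined. For mated against virgin it takes the 12 largest increases and 12 largest decreases among called genes whose 8 mated arrays all lay beyond every virgin array. For double against single mated it takes the 10 largest called changes in each direction, and for each mated group against virgin the 5 largest. It adds up to 4 called members of every list, by the smallest p for mated against virgin, and 14 genes chosen in advance. The rule gave 135 genes. AttA, DptA, CecA1 and TotM were among the 14 but had no probe set with 1 gene symbol, so they have no value here. Genes and families named outside the rule are said to have been chosen after their values were seen.

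For the correlation of the single and double mated changes, the value produced by shared virgin arrays alone was simulated 100 times, and the virgin arrays were also divided 2 and 2 between the comparisons in all 6 ways. The shares of single mated calls with the same sign or a larger change in double mated females were computed with divided virgin arrays as well, a check added after the data were seen. Alternatives covered the replicate number as a block, cyclic loess, centring each array on its median, filters on dim probe sets, the variance model, array weights, the threshold, the choice of probe set, the arrays in the fit, the gene set test and leaving out each array. A removal of each array's trend on gene length, and counts of list members without double mated replicate 4, were added after the data were seen. So were 6 ways of placing each mated array between the 2 mated groups on lists or probe sets called without it, and the 1 restricted to probe sets over 2-fold was made the test after all 6 had been seen, with mixed answers. Replicate numbers showed no consistent pairing of the arrays, though whether they mark batches is unknown. After removing group means, 1 of the 12 same-numbered pairs of arrays correlated above 0.1, and 2 of the 12 arrays correlated best with their own number. These pairs ran from -0.26, for the single and double mated arrays numbered 4, to 0.14. Plots were drawn in Python 3.11.15 with matplotlib 3.10.9.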

Results

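Transcript levels were measured on 12 arrays of whole adult females from LHM, a large outbred laboratory population of Drosophila melanogaster. Females were collected as virgins on day 9 and then kept as virgins, mated once, or mated on days 12 and 13, with 4 arrays in each group. The single mating is taken to be on day 13, since the deposited description keeps these females from males on day 12 and breaks off at the start of day 13. Mated females were frozen 6 hours after their last mating. All values are on the log2 scale, and group values are given as mean ± SD with n = 4 arrays. The title of the series names reproduction and the cost of mating in females as its subject.

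The groups separated on the first principal component, which carried 46.5% of the variance. Virgin arrays lay between -23.99 and -18.05 on it, single mated arrays between -1.84 and 8.78, and double mated arrays between 9.56 and 25.27. Double mated replicate 4 stood apart from its group: its difference from the other 3 double mated arrays had an SD of 0.26 over probe sets, against at most 0.19 for any other array. A limma array weight of 0.294 was the lowest of the 12.

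**Figure D1:**
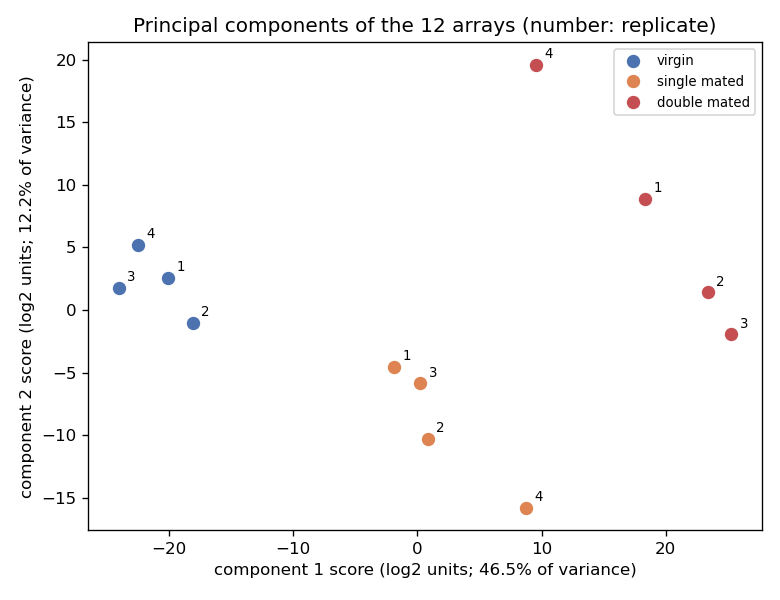
Principal components 1 and 2 of the 12 arrays, in log2 units, with 1 point per array and 1 colour per group. Virgin arrays lie at the low end of the first component, and double mated replicate 4, at 19.60 on the second component, lies away from the other double mated arrays.

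Mated females were compared with virgins to ask which transcripts differ after mating as such. The juvenile hormone genes jhamt and Kr-h1 were higher in mated females: jhamt, the enzyme that completes juvenile hormone synthesis, was 3.45-fold higher (95% interval 2.77 to 4.29), and Kr-h1, a transcription factor induced by the hormone, 3.11-fold higher (2.64 to 3.65). Of genes that digest dietary sugar, the maltase Mal-A7 fell to 0.233 of its virgin level (0.168 to 0.324) and the insulin-responsive glucosidase tobi to 0.243 (0.182 to 0.324). The largest increases were in Listericin, an antibacterial peptide, and CG17234, a protease of the sperm storage glands. These rose 6.90-fold (5.92 to 8.04) and 6.90-fold (3.42 to 13.9). All 8 mated arrays lay beyond all 4 virgin arrays for each of these 6 genes. Apart from Kr-h1, this separation was a condition for naming them and is not a separate finding.

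Of 18769 probe sets, 4594 changed with mating in limma, 1927 higher and 2667 lower, and 6402 had an unadjusted p under 0.05. Changes were mostly small, with a median size of 0.31 among those called. Increases beyond 2-fold numbered 77 and decreases 19. The F test called 4669 probe sets among the 3 groups. Further large increases were named under the same condition of separation. CG32751 rose 4.63-fold, CG8785 4.12-fold, the transporter gene MFS1 3.93-fold, CG31259 3.88-fold, the Osiris family gene Osi19 3.86-fold, vanin-like 3.72-fold and Cipc 3.64-fold. CG11912 and CG17192 rose by 1.78 (SE 0.20) and 1.68 (SE 0.19). Decreases with the same separation included Mal-A8 to 0.252 of the virgin level and Mal-B1 to 0.301, both maltases. Send1, a sperm storage gland protease, fell to 0.264. CG34040 fell to 0.314, CG8093 to 0.398, CG15263 to 0.410, the sorbitol dehydrogenase Sodh1 to 0.472, CG4363 to 0.473, the insulin-like peptide gene Ilp7 to 0.482 and the predicted gene CG6484 to 0.486.

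**Figure D2:**
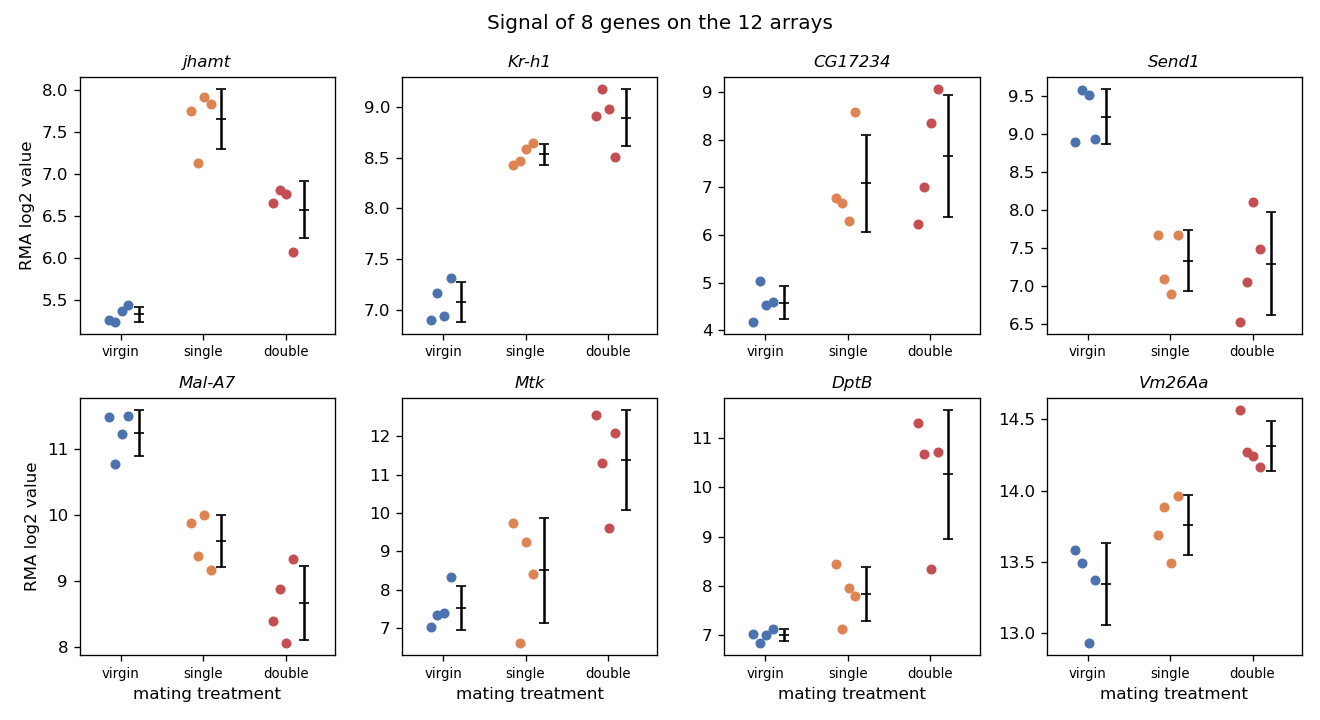
Log2 RMA values of 8 genes on each of the 12 arrays by group, with the mean and SD of each group of 4 arrays. The single mated arrays have the highest values of jhamt (mean 7.66, against 5.33 in virgins and 6.58 in double mated females), and the double mated arrays have the highest mean of Mtk, 11.38.

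Of 24 measured juvenile hormone and ecdysone genes, 6 rose and 2 fell, or 8 and 2 adjusted over the list alone, and the list was called higher (median change 0.14, adjusted p = 0.00448, and adjusted p = 0.225 with an estimated correlation, median 0.08 with each array centred on its median). Besides jhamt and Kr-h1, Jhe, an esterase that degrades juvenile hormone, rose by 0.97 (SE 0.09) and br, an ecdysone-responsive transcription factor, by 0.78 (SE 0.08). Of 14 postmating neural and oviduct genes, 4 rose and 1 fell, or 5 and 2 adjusted over the list alone (adjusted p = 0.0882). In this list the sex-determination factor dsx rose by 1.06 (SE 0.10), the matrix protease Mmp2 by 0.61 (SE 0.08) and SPR, the sex peptide receptor, by 0.53 (SE 0.08), while Ilp7 fell by 1.05 (SE 0.14). Of 15 insulin and nutrient genes, 4 rose and 1 fell, the same counts as adjusted over the list alone (adjusted p = 0.214). AkhR, the adipokinetic hormone receptor, rose by 0.36 (SE 0.07) and the insulin-binding protein gene ImpL2 by 0.42 (SE 0.07), and Ilp8 fell by 0.71 (SE 0.10). The rise of AkhR lay in the double mated group, as its change between the mated groups below shows. Of 10 clock genes, 5 rose and 1 fell, the same counts as adjusted over the list alone (adjusted p = 0.00835, and adjusted p = 0.225 with an estimated correlation). The clock repressor cwo rose by 0.53 (SE 0.07), Pdp1 by 0.57 (SE 0.09) and vri by 0.47 (SE 0.06).

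Several of the reproductive lists changed in these whole-female extracts, which do not show the tissue of a change. Eggshell proteins, made by the follicle cells, had 8 of 17 members higher and none lower, or 11 adjusted over the list alone, with a median change of 0.56 (adjusted p = 8.24e-05, and adjusted p = 0.280 with an estimated correlation). Vm32E rose by 1.12 (SE 0.19), psd by 1.05 (SE 0.12), dec by 0.98 (SE 0.15) and Vm26Aa by 0.69 (SE 0.12). Yolk and lipid transport genes had 5 of 9 higher and none lower, also when adjusted over the list alone (adjusted p = 0.00315, and adjusted p = 0.225 with an estimated correlation). Apoltp, a lipid transfer particle, rose by 1.14 (SE 0.09), the lipophorin receptor LpR2 by 0.36 (SE 0.06), apolpp by 0.26 (SE 0.05) and the yolk protein Yp2 by 0.25 (SE 0.05). The rise of LpR2 lay in the double mated group, as its change between the mated groups below shows. Changes of Yp1 (0.10, SE 0.04, adjusted p = 0.124) and Yp3 (0.09, SE 0.04, adjusted p = 0.185) did not pass, and passed once a trend on gene length was removed (0.23, adjusted p = 0.00114, and 0.20, adjusted p = 0.00213).

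Of 12 sperm storage gland genes, 8 rose and 2 fell, the same counts as adjusted over the list alone (median 0.48, adjusted p = 0.0179, and adjusted p = 0.225 with an estimated correlation). CG17239 rose by 0.89 (SE 0.16) and Bbd by 0.72 (SE 0.09), against the decrease of Send1. DNA replication genes, active in dividing and follicle cells, had 10 of 14 members lower and none higher, or 11 adjusted over the list alone, with a median change of -0.37 (adjusted p = 2.37e-04, and adjusted p = 0.404 with an estimated correlation). Mcm3 fell by 0.48 (SE 0.09), the replication clamp PCNA by 0.45 (SE 0.06), Orc5 by 0.55 (SE 0.08) and RnrL by 0.47 (SE 0.09). Of 23 germline and maternal genes 3 rose and 8 fell, or 3 and 9 adjusted over the list alone (adjusted p = 0.133). The translation regulators png and plu fell by 0.48 (SE 0.08) and 0.37 (SE 0.05), stwl fell by 0.48 (SE 0.08), and orb rose by 0.41 (SE 0.08).

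Midgut serine proteases had 15 of 24 members higher and none lower, or 18 adjusted over the list alone, with a median change of 0.42 (adjusted p = 8.31e-09, and adjusted p = 0.225 with an estimated correlation). Jon99Fi rose by 1.21 (SE 0.16), lambdaTry by 0.65 (SE 0.10), Jon65Aiii by 0.59 (SE 0.07) and yip7 by 0.43 (SE 0.06). In the list of gut carbohydrases, lipase and lysozymes, 5 of 20 rose and 10 fell, or 6 and 11 adjusted over the list alone (adjusted p = 0.204). Of 10 maltases, a family chosen after its values were seen, 8 fell, the other decreases being tobi and the amylase-related Amyrel. Among the increases were the alpha-mannosidases LManVI (0.92, SE 0.15) and LManV (0.61, SE 0.13), also chosen after their values were seen.

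Antimicrobial peptides had 7 of 8 measured members higher, the same count as adjusted over the list alone, with a median change of 0.48 (adjusted p = 2.92e-04, and adjusted p = 0.0733 with an estimated correlation). The fixed list had 22 members, of which 14 lacked a probe set with 1 gene symbol. Mtk rose by 2.42 (SE 0.56), DptB by 2.04 (SE 0.40), Def by 0.86 (SE 0.09) and BomS2 by 0.44 (SE 0.10). The rise of this list lay mostly in the double mated group, since 0 of 8 members were called for single mated females against virgins. BomS2 averaged 11.32 in virgins, 11.09 in single mated and 12.43 in double mated females. Drs, an antifungal peptide of the Toll response, rose by 0.23 (SE 0.06), and its call ended without virgin replicate 1 (adjusted p = 0.0613), without virgin replicate 2 (0.0685) and with each array centred on its median (0.0566). Hemocyte markers had 5 of 10 higher, or 6 adjusted over the list alone, with a median of 0.23 (adjusted p = 2.92e-04, and adjusted p = 0.0733 with an estimated correlation). The blood cell factor srp rose by 0.87 (SE 0.11), the collagen vkg by 0.62 (SE 0.07), NimB2 by 0.57 (SE 0.08) and Col4a1 by 0.49 (SE 0.06). Of 16 peptidoglycan recognition and Imd genes, 2 rose and 3 fell, or 3 and 4 adjusted over the list alone (adjusted p = 0.795), with PGRP-SB1 up by 1.11 (SE 0.26) and the kinase subunits key and IKKbeta down, at -0.33 (SE 0.04) and -0.35 (SE 0.07). Of 15 Toll pathway genes, 1 rose and 3 fell, the same as adjusted over the list alone (adjusted p = 0.518), with nec up by 0.25 (SE 0.06). The rise of nec lay mostly in the double mated group. Melanization had 1 of 9 higher by either count (adjusted p = 0.414). Turandot and JAK/STAT genes had 0 of 9 called in limma by either count and 2 at an unadjusted p under 0.05 (adjusted p of the list = 0.235).

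Muscle structural genes had 12 of 16 higher and none lower, or 13 adjusted over the list alone, with a median of 0.43 (adjusted p = 2.56e-07, and adjusted p = 0.225 with an estimated correlation), and Act87E rose by 0.86 (SE 0.08), Prm by 0.63 (SE 0.08), TpnC73F by 0.60 (SE 0.09) and Mlp60A by 0.50 (SE 0.07). Photoreceptor genes had 6 of 9 higher and 1 lower, the same as adjusted over the list alone, with a median of 0.25 (adjusted p = 0.00412, and adjusted p = 0.225 with an estimated correlation). Arr1, trp and inaC rose by 0.37 (SE 0.06), 0.40 (SE 0.06) and 0.43 (SE 0.06), and rdgB fell by 0.34 (SE 0.06). Neuronal genes had 3 of 12 higher by either count, with a median of 0.15 (adjusted p = 0.0114, and adjusted p = 0.280 with an estimated correlation, median 0.09 with each array centred on its median and 0.05 with the length trend removed), among them Gad1 (0.53, SE 0.06) and VAChT (0.47, SE 0.07). Fat body storage and lipogenesis genes had 6 of 16 higher and 1 lower, or 8 and 1 adjusted over the list alone (median 0.16, adjusted p = 0.00448, and adjusted p = 0.0854 with an estimated correlation, median 0.09 with each array centred on its median). The lipid droplet protein Lsd-1 rose by 0.67 (SE 0.11), AcCoAS by 0.65 (SE 0.08), FASN2 by 0.50 (SE 0.07) and Desat1 by 0.35 (SE 0.06).

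Of 29 male accessory gland genes, 1 rose, and 0 were called when adjusted over the list alone, with 3 at an unadjusted p under 0.05 (adjusted p of the list = 0.235). The member that rose, Mst57Da, went from 3.78 ± 0.08 in virgins to 3.94 ± 0.07 and 3.95 ± 0.08 in single and double mated females, and its call ended under 11 of the 18 alternatives. SP, the sex peptide gene, measured 4.03 ± 0.06 in virgins, 4.17 ± 0.12 in single mated and 4.03 ± 0.10 in double mated females (adjusted p = 0.457). Acp26Aa, the ovulin gene, measured 3.59 ± 0.13, 3.59 ± 0.02 and 3.58 ± 0.22 (adjusted p = 0.958). Testis and sperm genes had 0 of 22 called in limma by either count and 1 at an unadjusted p under 0.05 (adjusted p of the list = 0.673).

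Proteasome subunits had 21 of 26 members lower and none higher, or 23 adjusted over the list alone, with a median of -0.25 (adjusted p = 8.31e-09, and adjusted p = 0.198 with an estimated correlation, median -0.12 with the length trend removed). Rpn12 fell by 0.45 (SE 0.05), Prosalpha7 by 0.35 (SE 0.05), and Prosalpha3 and Prosalpha6 by 0.32 (SE 0.05) each. Odorant-binding proteins had 9 of 47 higher and 2 lower by either count, with a median of 0.05 that became -0.01 with each array centred on its median (adjusted p = 0.0423, and adjusted p = 0.456 with an estimated correlation). Obp56a rose by 0.97 (SE 0.11), Obp83ef by 0.92 (SE 0.15) and Obp56d by 0.53 (SE 0.09), and Obp99b fell by 0.51 (SE 0.09). Cytochromes P450 had 16 of 83 higher and 15 lower, or 17 and 16 adjusted over the list alone (adjusted p = 0.396), with Cyp4p3 up by 0.85 (SE 0.10), Cyp313a4 up by 0.80 (SE 0.11), Cyp6g1 down at -0.81 (SE 0.11) and Cyp28d1 down at -0.67 (SE 0.08). Glutathione and UDP transferases had 6 of 69 higher and 11 lower by either count (adjusted p = 0.795), with GstD9 up by 0.30 (SE 0.06) and Ugt304A1 down at -0.42 (SE 0.06). Heat shock genes had 2 of 7 higher and 2 lower by either count (adjusted p = 0.873), Hsp68 rising by 0.27 (SE 0.07) and Hsp26 falling by 0.58 (SE 0.09). Ribosome biogenesis had 2 of 12 higher by either count (adjusted p = 0.157), including Nnp-1 (0.29, SE 0.06). Ribosomal proteins had 1 of 34 lower, and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05 (adjusted p = 0.647).

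In all, 15 of 30 lists were called for mated against virgin, 13 higher and 2 lower, and none of the 15 calls held with an estimated correlation. Calls also ended for the odorant-binding list under cyclic loess (adjusted p = 0.161) and without virgin replicate 4 or double mated replicate 1, 2 or 3 (0.0610 to 0.0761), for the neuron list under cyclic loess (0.0815) and with the length trend removed (0.213), and for the clock list with the length trend removed (0.0683). The share of changed probe sets that were higher, 41.9%, was 53.0% under cyclic loess (2211 higher and 1959 lower) and 26.3% with each array centred on its median (1429 and 3996). The peptidoglycan recognition list was the 1 list of the 30 whose median, mean and test differed in sign.

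**Figure D3:**
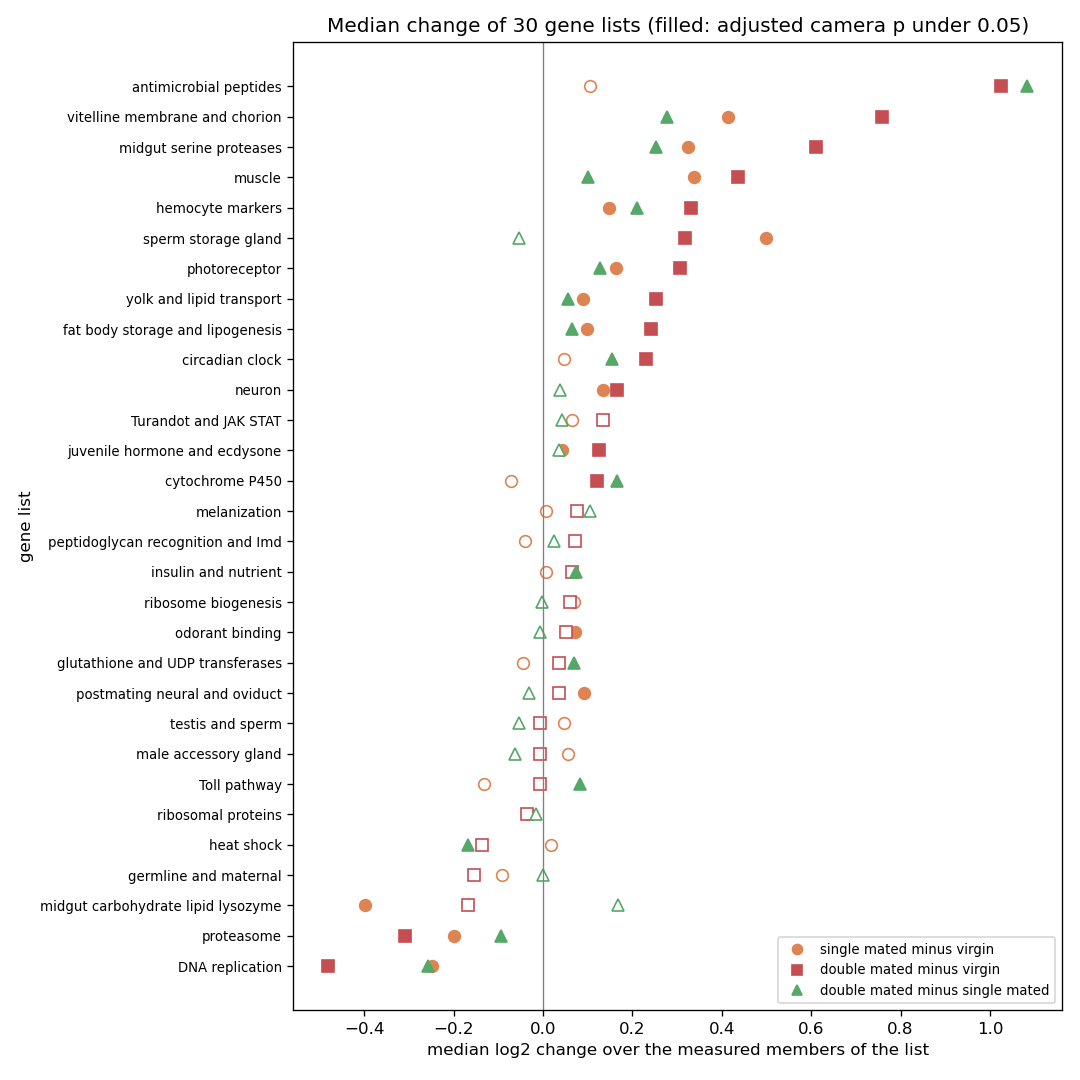
Median log2 change of the members of each of the 30 gene lists in 3 comparisons, each group of mated females against virgins and double against single mated, with filled points for lists called by limma camera at the preset correlation. The largest list medians are those of the antimicrobial peptides, 1.03 for double mated against virgin and 1.08 for double against single mated, and DNA replication genes have the lowest, -0.48 for double mated against virgin.

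Single mated females were compared with virgins to show the state 6 hours after 1 mating. The hormone gene jhamt rose 5.01-fold (95% interval 3.90 to 6.45), from 5.33 ± 0.09 to 7.66 ± 0.36, Jhe 2.69-fold (2.28 to 3.16) and Kr-h1 2.74-fold (2.27 to 3.30). MFS1 rose 5.42-fold (4.01 to 7.33) and CG17234 5.65-fold (2.51 to 12.7). The sugar-digesting genes Mal-A8, Mal-B1 and tobi fell, to 0.222 of the virgin level (0.148 to 0.334), 0.272 (0.196 to 0.377) and 0.293 (0.210 to 0.409). Of the antimicrobial peptides, 0 of 8 were called in limma, also when adjusted over the list alone and at an unadjusted p under 0.05, with Mtk at 0.98 (SE 0.64, adjusted p = 0.381) and the list at an adjusted p of 0.318. Among immune genes outside that list, Listericin rose 4.29-fold (3.60 to 5.12).

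In limma, 1813 probe sets changed after 1 mating, 843 higher and 970 lower, 61 and 16 of them beyond 2-fold, and 4658 had an unadjusted p under 0.05. Osi19 rose 4.61-fold and CG31259 4.70-fold, while Send1 and Mal-A7 fell to 0.268 and 0.323 of the virgin level. Midgut serine proteases had 8 of 24 higher, or 9 adjusted over the list alone (median 0.32, adjusted p = 1.69e-07, and adjusted p = 0.30 with an estimated correlation). Muscle genes had 7 of 16 higher, or 9 adjusted over the list alone (median 0.34, adjusted p = 1.39e-07, and adjusted p = 0.30 with an estimated correlation). Proteasome subunits had 11 of 26 lower, or 17 adjusted over the list alone (median -0.20, adjusted p = 5.62e-08, and adjusted p = 0.236 with an estimated correlation, median -0.10 with the length trend removed). Eggshell genes had 1 of 17 higher, psd, or 4 adjusted over the list alone (median 0.41, adjusted p = 0.00181, and adjusted p = 0.356 with an estimated correlation). DNA replication genes had 2 of 14 lower, PCNA and Orc5, or 5 adjusted over the list alone (adjusted p = 0.00549, and adjusted p = 0.436 with an estimated correlation). The gut carbohydrase list had 9 of 20 lower and 2 higher, or 11 and 4 adjusted over the list alone (median -0.40, adjusted p = 0.0358, and adjusted p = 0.356 with an estimated correlation). Juvenile hormone and ecdysone genes had 6 of 24 higher, or 8 higher and 2 lower adjusted over the list alone (adjusted p = 0.00841, and adjusted p = 0.30 with an estimated correlation), and the list median, 0.04, became -0.02 with each array centred on its median. Sperm storage gland genes had 6 of 12 higher and 1 lower, or 8 and 1 adjusted over the list alone (median 0.50, adjusted p = 0.0132, and adjusted p = 0.30 with an estimated correlation). Hemocyte markers had 5 of 10 higher by either count (median 0.15, adjusted p = 0.00450, and adjusted p = 0.225 with an estimated correlation, median 0.09 with each array centred on its median).

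Called lists numbered 15 of 30, 12 higher and 3 lower, and none held with an estimated correlation, where adjusted p ran from 0.225 upward. The call of the gut carbohydrase list ended without virgin replicate 1 (adjusted p = 0.0721), virgin replicate 4 (0.0525), single mated replicate 1 (0.0550) or double mated replicate 4 (0.0732), and with camera on ranks (0.116), which also ended the calls of the hormone (0.0827), postmating (0.0743) and yolk (0.0538) lists. Calls of the postmating, odorant-binding and neuron lists ended in at least 1 further setting each, with adjusted p from 0.0505 to 0.252. The count of changed probe sets was 1159 without virgin replicate 1, 883 without virgin replicate 3 and 857 without single mated replicate 4, and the share higher, 46.5%, was 63.2% under cyclic loess (987 higher and 574 lower) and 25% with each array centred on its median (641 and 1926).

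Double mated females were compared with virgins to show the state after matings on successive days. Several immune peptide genes rose: Mtk, encoding the antifungal metchnikowin, rose 14.5-fold (95% interval 5.57 to 37.7), Listericin 11.1-fold (9.31 to 13.3), DptB 9.53-fold (4.79 to 19.0) and Def 3.10-fold (2.65 to 3.62). CG17234 rose 8.43-fold (3.74 to 19.0), and the hormone genes Kr-h1 and jhamt rose 3.52-fold (2.92 to 4.24) and 2.37-fold (1.84 to 3.05). Mal-A7 fell to 0.169 of the virgin level (0.116 to 0.246) and tobi to 0.201 (0.144 to 0.280), and the trypsin gene Try29F to 0.266 (0.159 to 0.445). The eggshell gene Vm32E rose 3.15-fold (2.28 to 4.36) and psd 2.95-fold (2.41 to 3.60).

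In this comparison limma called 5268 probe sets changed, 2314 higher and 2954 lower, 143 and 22 of them beyond 2-fold, with 6905 at an unadjusted p under 0.05. Antimicrobial peptides had 7 of 8 higher by either count, with a median of 1.03 (adjusted p = 1.04e-05), and this was the 1 call of 15 that held with an estimated correlation (adjusted p = 0.0366). Midgut serine proteases had 18 of 24 higher, or 19 adjusted over the list alone (median 0.61, adjusted p = 2.77e-08, and adjusted p = 0.227 with an estimated correlation). Eggshell genes had 9 of 17 higher, or 12 adjusted over the list alone (median 0.76, adjusted p = 4.25e-05, and adjusted p = 0.258 with an estimated correlation). DNA replication genes had 11 of 14 lower by either count (median -0.48, adjusted p = 6.79e-05, and adjusted p = 0.363 with an estimated correlation). Proteasome subunits had 22 of 26 lower, or 23 adjusted over the list alone (median -0.31, adjusted p = 3.00e-08, and adjusted p = 0.226 with an estimated correlation, median -0.18 with the length trend removed). Muscle genes had 11 of 16 higher, or 12 adjusted over the list alone (median 0.44, adjusted p = 2.15e-06, and adjusted p = 0.242 with an estimated correlation), and hemocyte markers 7 of 10 by either count (median 0.33, adjusted p = 1.09e-04, and adjusted p = 0.0531 with an estimated correlation). Fat body genes had 7 of 16 higher and 1 lower, or 8 and 1 adjusted over the list alone (adjusted p = 0.00348, and adjusted p = 0.0737 with an estimated correlation). Without double mated replicate 4, the counts were 7 antimicrobial peptides, 20 midgut proteases, 12 eggshell genes, 14 DNA replication genes and 23 proteasome subunits in the same directions, with 1 eggshell gene lower. The share of changed probe sets that were higher, 43.9%, was 53.4% under cyclic loess (2682 higher and 2341 lower) and 29.1% with each array centred on its median (1777 and 4326).

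Among probe sets called after a single mating, 97.2% had the same sign in double mated females and 75.4% a larger change there, with the same virgin arrays in both comparisons. With the virgin arrays divided 2 and 2 between the comparisons, these shares averaged 95.2% and 59.9%, and 68.7% of all probe sets had the same sign. In both comparisons 739 probe sets rose and 852 fell, against 104 and 153 if the lists were independent, and 17 went in opposite directions. Among these were CG6830, at 8.70 ± 0.28 in single mated, 9.58 ± 0.17 in virgin and 10.12 ± 0.12 in double mated females, and Ugt37A2, a sugar transferase of detoxification, at 6.68 ± 0.28, 7.63 ± 0.20 and 8.29 ± 0.23. Across probe sets, which are not independent replicates, the changes correlated at r = 0.789 with a covariance of 0.0482. Shared virgin arrays alone gave 0.501 and 0.00509 in simulations without any effect, and dividing the virgin arrays 2 and 2 gave an average r of 0.689 and covariance of 0.0446. With divided virgin arrays, an average of 332 probe sets rose and 163 fell in both comparisons, against 28.7 and 16.4 for independent lists.

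Double mated females were compared with single mated females to ask what the additional mating added. Peptides of the immune response rose: Mtk 7.37-fold (95% interval 2.83 to 19.2), DptB 5.38-fold (2.70 to 10.7), Def 2.93-fold (2.50 to 3.43), Listericin 2.59-fold (2.17 to 3.09) and BomS2, a Bomanin, 2.53-fold (2.14 to 3.00). The eggshell genes Vm32E and psd rose 2.11-fold (1.53 to 2.92) and 2.03-fold (1.66 to 2.48). The juvenile hormone genes jhamt and Jhe fell, to 0.472 of the single mated level (0.367 to 0.608) and 0.530 (0.451 to 0.624), while their list was not called, with 2 of 24 higher and 2 lower, or 5 and 3 adjusted over the list alone (adjusted p = 0.303). The change of Kr-h1, 1.28-fold (1.07 to 1.55), did not pass (adjusted p = 0.110).

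Limma called 992 probe sets, 666 higher and 326 lower, 42 and 7 of them beyond 2-fold, with 4055 at an unadjusted p under 0.05. Without double mated replicate 4 it called 1186 higher and 985 lower, and with array weights 1207 and 988, so that 54.6% and 55% were higher against 67.1%. The virgin arrays enter this test through the estimate of variance, and with the 8 mated arrays alone it called 550. Antimicrobial peptides had 5 of 8 higher and none lower, or 7 adjusted over the list alone, with a median of 1.08 (adjusted p = 8.01e-09). Scores of this list per array ran from 0.38 to 1.16 in double mated females and from -0.64 to -0.17 in single mated females (exact permutation test, 2-sided, p = 0.0286, the smallest that 4 against 4 arrays allow). This test was not planned and was run only on this list and the hemocyte and cytochrome P450 lists, without adjustment over the 30 lists. All of them gave the same p, so it adds no separate support to the list call. For Mtk the call ended without double mated replicate 1 (adjusted p = 0.0521) and with an intensity trend in the variance model (0.0697), with changes of 2.49 and 2.88. Hemocyte markers had 3 of 10 higher, or 4 adjusted over the list alone, NimB2, Col4a1 and vkg rising by 0.43 (SE 0.09), 0.32 (SE 0.07) and 0.30 (SE 0.08), with a list median of 0.21 (adjusted p = 3.15e-04). Cytochromes P450 had 21 of 83 higher and 2 lower, or 30 and 7 adjusted over the list alone (median 0.17, adjusted p = 5.53e-06). Cyp4p3 rose by 0.55 (SE 0.11) and Cyp28d1 by 0.34 (SE 0.09), Cyp313a4 fell by 0.56 (SE 0.12), and the largest increase of the family, chosen after its values were seen, was Cyp12a5 at 1.16 (SE 0.10). With an estimated correlation, 3 of the 16 list calls held, those of the antimicrobial peptides (adjusted p = 0.00556), cytochromes P450 (0.0405) and hemocyte markers (0.0425).

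The other 13 lists, among them those of Toll, yolk, fat body, muscle and photoreceptor genes, were called at the preset correlation alone. Eggshell genes had 5 of 17 higher, or 6 adjusted over the list alone (median 0.28, adjusted p = 5.95e-04, and adjusted p = 0.396 with an estimated correlation). DNA replication genes had 3 of 14 lower, PCNA, Orc5 and Mcm3, or 8 adjusted over the list alone (median -0.26, adjusted p = 3.15e-04, and adjusted p = 0.440 with an estimated correlation). Midgut serine proteases had 4 of 24 higher, or 9 adjusted over the list alone (median 0.25, adjusted p = 2.09e-04, and adjusted p = 0.398 with an estimated correlation). Glutathione and UDP transferases had 7 of 69 higher and 3 lower, or 13 and 3 adjusted over the list alone (adjusted p = 0.00329, and adjusted p = 0.381 with an estimated correlation), led by Ugt37A2 at 1.60 (SE 0.14). Insulin and nutrient genes had 3 of 15 higher, or 4 adjusted over the list alone (adjusted p = 0.0176, and adjusted p = 0.139 with an estimated correlation), with AkhR up by 0.70 (SE 0.08) and ImpL2 by 0.51 (SE 0.08). Clock genes had 2 of 10 higher by either count (adjusted p = 0.00532, and adjusted p = 0.243 with an estimated correlation), among them vri at 0.56 (SE 0.07). Heat shock genes had 1 of 7 lower, Hsp26 at -0.41 (SE 0.11), or 3 adjusted over the list alone (adjusted p = 0.0121, and adjusted p = 0.381 with an estimated correlation). Proteasome subunits had 1 of 26 lower by either count, Rpn12 at -0.25 (SE 0.06), with a list median of -0.09 (adjusted p = 0.00106, and adjusted p = 0.381 with an estimated correlation, median -0.06 under cyclic loess and -0.05 with the length trend removed). In the Toll list nec rose by 0.43 (SE 0.07), and in the yolk and lipid transport list LpR2 rose by 0.71 (SE 0.07).

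Further large increases, all outside the lists, were in CG13947 (1.53, SE 0.18), the caspase gene Damm (1.52, SE 0.21), CG6830 (1.42, SE 0.12), CG13309 (1.39, SE 0.25) and CG13482 (1.37, SE 0.26). CG12998 had the largest decrease, to 0.362 of the single mated level (0.298 to 0.440). The metallothionein genes MtnD and MtnB, which bind heavy metals, fell to 0.419 and 0.526, and MtnD measured 9.11 ± 0.33 in virgins, 10.36 ± 0.40 in single mated and 9.11 ± 0.44 in double mated females. CG10013 fell to 0.426, CG33510 to 0.463, CG4830 to 0.478, CG4563 to 0.499, Mal-A7 to 0.523 and MFS1 to 0.524. The decreases of MtnB, MFS1 and Mal-A7 lay near the threshold: their calls ended without single mated replicate 2 (MtnB, adjusted p = 0.0516), without single mated replicate 1 or double mated replicate 3 (MFS1, 0.0501 and 0.0521), and for Mal-A7 under 11 of the 20 alternatives.

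Leaving out double mated replicate 4 raised the count of changed probe sets from 992 to 2171, while it was 616, 527 or 594 without single mated replicate 1, 2 or 3 and 613 or 648 without double mated replicate 2 or 3. Without double mated replicate 4, 5 antimicrobial peptides (median 0.97), 4 hemocyte markers, 5 eggshell genes, 9 midgut proteases and 24 cytochromes P450 rose, and 11 DNA replication genes and 6 cytochromes P450 fell. Calls of 6 of the 13 lists named last ended in at least 1 further setting: Toll (adjusted p up to 0.30, without this array), fat body (up to 0.116, without single mated replicate 2), muscle (up to 0.0928, without single mated replicate 1), yolk (up to 0.0771, with the mean of all probe sets of a gene), and insulin (0.117) and photoreceptor (0.0755) with the length trend removed. Median, mean and test differed in sign for 4 lists here, none of them called: germline, sperm storage gland, ribosome biogenesis and odorant-binding.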

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

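The tests of other divisions of the arrays were fixed before the results were seen, and every other test in this part was chosen only after the result it weighs had been seen. An array is listed here when its gap to the nearest of the other 3 arrays of its group, divided by the range of the group, exceeded Dixon's 95% critical value for 4 samples. This held for 33 of 495 groups tested, and chance alone gives about 1 in 20 groups, or 24.8. Double mated replicate 4 accounts for 10, single mated replicate 4 for 7 and virgin replicate 4 for 3, and no other array for more than 2.

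Double mated replicate 4 lay below the other 3 arrays for Def (8.98, against 9.28 to 9.33), Damm (8.49), CG13309 (8.75), MtnB (6.88), vri (8.68), Obp56a (9.56) and Prosalpha3 (12.22), and above them for spz (10.33) and RpS5b (14.28). Its score of the ribosomal protein list was -0.18, against 0.00046 to 0.026. Single mated replicate 4 was high for CG17239 (9.81) and Nnp-1 (11.79), low for Ilp8 (9.59), rdgB (8.76), VAChT (5.56) and Prosalpha7 (12.03), and high in the testis and sperm score (0.081). Virgin replicate 4 was low for CG13947 (8.88) and high for SPR (7.52) and inaC (7.81).

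Single values of this kind on the other arrays were as follows. Virgin replicate 1 was low for Mst57Da (3.66) and Rpn12 (12.48), virgin replicate 2 low for CG10013 (6.84) and high for Mmp2 (6.35), and virgin replicate 3 low for dec (10.65). Single mated replicate 1 was low for SPR (7.60) and in the neuron score (0.0052), single mated replicate 2 low for Csp (10.14), and single mated replicate 3 low for Ugt304A1 (5.29) and Ugt301D1 (8.54). Double mated replicate 1 was high for Vm32E (12.29) and low in the testis and sperm score (-0.067), and double mated replicate 3 was high for yip7 (14.61).

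Whether other divisions of the arrays call as much was tested with limma for each result. Of the 35 ways to divide the 8 arrays of 2 groups, 1, the real one, called as many probe sets for single mated against virgin (1813, with 0 the most in any other and up to 2405 at an unadjusted p under 0.05) and 1 for double mated against virgin (5268, 0 and 3962). For double against single mated, 2 of 35 did, since exchanging the 2 arrays numbered 4 called 1042 against 992, so chance is not excluded at 0.05 for this count. For list calls the numbers were 1 of 35 (15 lists, at most 11 elsewhere), 6 of 35 (15, at most 17) and 1 of 35 (16, at most 13) in the same order, so chance is not excluded for the number of lists called in double mated against virgin. Among 100 divisions of all 12 arrays, 1 called as many in the F test (4669, at most 906 elsewhere), 1 for mated against virgin (4594, at most 16) and 1 for its lists (15, at most 14).

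Muscle, photoreceptor, hemocyte and fat body lists were higher and proteasome and DNA replication lists lower in mated females. A lower share of ovary RNA would move tissue lists alike only if their members were not expressed in the ovary. That was not examined, so unequal moves cannot exclude it. With the neuron list included, 5 of 10 pairs of tissue lists moved apart (exact permutation over 495 divisions of the arrays, adjusted p = 0.0337 to 0.0364). Each of these pairs held the muscle or hemocyte list. Photoreceptor, neuron and fat body lists did not move apart from each other (adjusted p = 0.756 to 0.909 in this test). The eggshell list, made in the ovary, rose by a median of 0.56 (SE 0.19), which argues against an equal fall of all ovary RNA. This SE comes from resampling list members as if they were independent and does not measure the spread over arrays. The germline list, not called, had 8 of 23 members lower and 3 higher (median -0.10), so a lower ovary share remains open. A brightness trend left by the normalization would end these calls under cyclic loess, and 6 of 6 kept call and direction at the preset correlation, while with an estimated correlation none of the 6 was called (adjusted p = 0.0733 to 0.404). For the neuron list, with an adjusted p of 0.0815 under cyclic loess and a median of 0.12 against 0.15, the trend and a tissue change cannot be told apart. A response of these tissues to mating remains a hypothesis that was not tested separately.

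Antimicrobial peptides were higher in double than in single mated females. An infection in 1 pool would leave the list unchanged without that pool, but the median was at least 0.97 whichever double mated array was left out, with an adjusted p of at most 1.90e-06 and of at most 0.0181 with an estimated correlation. A larger share of blood cell and fat body RNA would raise those lists as much, and their medians were 0.21 (SE 0.07) and 0.07 (SE 0.07) against 1.08 (SE 0.52). These SE come from resampling list members as if they were independent and do not measure the spread over arrays. The difference between the lists was not tested over arrays. The earlier mating itself remains a hypothesis that was not tested, and the double mated group differs from the single mated group also in time since the first mating. Other causes shared by all double mated pools were not tested.

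Double mated replicate 4 lay apart from its group. Of 63 probe sets called without it and over 2-fold between the groups, it lay nearer double mated on 40 (63.5%, at most 13.0% for a single mated array left out in turn, at least 87.2% for another double mated one), which argues against a pool of single mated females alone under this label. This is 1 of 6 placements computed, and the others were mixed. Replicate 4 lay nearer double mated on 6 of 15 called lists (at most 6 of 16 for a single mated array) and on 39.4% of called probe sets (at most 28.9%). It lay beyond every single mated array on 50.8% (at most 60.7%), but a single mated array had to pass only the other 3, an easier bar. Its median share of the way from single to double mated was 0.34 (at most 0.30 for a single mated array, at least 0.82 for another double mated one). It went over 3/4 of the way on 23.9% of probe sets (at most 10.5% and at least 57.0%). An intermediate or mixed pool, which was not tested, stays open. Exchanged labels of the 2 arrays numbered 4 would place both nearer the other group, and 25.4% of 2449 probe sets did so. On these, single mated replicate 4 lay a median of 0.39 of the way from single to double mated, and double mated replicate 4 lay 0.34. Signal loss by transcript length was not tested, since the trend removed was on gene length. The SD of the difference of double mated replicate 4 from the other 3 arrays was 0.25 after removing that trend and 0.26 before, against at most 0.18 elsewhere after removal. Among abundant genes this difference correlated with gene length at 0.51 (Spearman), against -0.40 to 0.35 elsewhere. Its SD over ribosomal proteins was 0.42, against at most 0.15 elsewhere. Embryos held inside the females and another cause cannot be told apart, since 10 of 18 dim patterning genes, a class chosen after other embryo genes were seen high here, had their highest value on this array (at most 2 on any other array), but only 1 by more than 0.5 log2 units.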

How the results depend on the processing

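Removal of the gene length trend and counts without double mated replicate 4 were chosen after the data had been seen, and the other alternatives before. Of 600 list results under other settings, 559 stayed on the same side of the threshold, 27 lost the call, 11 gained it and 3 reversed. A change of direction was counted only for results called as deposited or under the alternative, so uncalled results may have changed direction. For named genes the counts were 1257, 15 and 4 of 1276. With 1 array left out at a time, 1394 of 1440 list results and 1891 of 1932 gene results stayed the same. Most named genes were chosen as called in the fit to these same arrays, so the gene counts are partly fixed by that choice. The reversed results are the ribosomal protein list, uncalled as deposited and called higher with the length trend removed (adjusted p = 0.00618 for mated, 0.00992 for single mated and 0.0129 for double mated against virgin). With an estimated correlation 57 of 120 list results lost their call, and 0, 0, 1 and 3 lists were called for mated, single mated and double mated against virgin and double against single mated, against 15, 15, 15 and 16. The estimate was 0.863 for DNA replication, 0.536 for muscle, 0.462 for midgut serine protease and 0.425 for eggshell genes, far above the preset 0.01. A higher correlation makes the list test stricter. For the fat body list it was 0.001, and that call was lost too. For the postmating list it was -0.011, yet the adjusted p for mated against virgin rose from 0.0882 to 0.225. The correlation thus does not account for every loss, and a lost call cannot be read as an effect of correlation alone. Other causes of the changes in this paragraph were not tested.

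With a replicate block, 661 probe sets changed between double and single mated, and 4173, 1305 and 4830 in the comparisons with virgin. Array weights gave 2953 for single mated against virgin and 2195 for double against single mated. An adjusted p under 0.01 gave 2866, 606 and 307 for mated against virgin, single mated against virgin and double against single mated, and 2898 in the F test, a stricter threshold by construction. A test against 1.2-fold gave 466, 113, 1119 and 61, also by construction stricter. With the 8 compared arrays alone, 550 probe sets changed between double and single mated. The correlation of single and double mated changes was 0.689 with the virgin arrays divided and 0.814 for probe sets with a mean of at least 5. Apart from the thresholds, the cause was not tested.

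Leaving out 1 array at a time gave 3415 to 5445 probe sets for mated against virgin, 857 to 2698 for single mated and 4333 to 5975 for double mated against virgin, 527 to 2171 for double against single mated and 3636 to 5620 in the F test. The correlation ran from 0.766 to 0.802. Lists called ran from 14 to 15, 13 to 16, 13 to 15 and 13 to 16 in the same order of comparisons. The highest counts of probe sets all came without double mated replicate 4.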

Other observations

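Families in this part were chosen only after their values had been seen, and no test of them as groups was made. Bomanins, short peptides secreted in the Toll response, had 7 of 8 members higher in double than in single mated females (median 0.99) and 3 of 8 lower in single mated females than in virgins (median -0.38). Alkaline phosphatases had 7 of 12 higher in mated females than in virgins (median 0.41). Of 4 metallothioneins, 2 were higher in single mated females than in virgins (median 0.48) and 2 lower in double than in single mated females (median -0.50). Mitochondrial ribosomal proteins had 22 of 69 lower in mated females (median -0.12, and -0.041 under cyclic loess).

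Z600, halo and SNCF, genes of the early embryo, were highest on double mated replicate 4 (7.10, 6.64 and 6.98), with 4.03, 4.54 and 5.19 on double mated replicate 1, 5.53, 5.83 and 5.87 on replicate 2 and 5.79, 5.98 and 6.24 on replicate 3. Their means in virgins were 4.14, 4.29 and 4.92, and double mated replicate 1 lay near them. For double mated females against virgins all 3 were called higher (adjusted p = 0.0175, 0.00229 and 0.00348). On double mated replicate 4 the ribosomal protein genes RpL40 and RpS18 measured 12.67 and 13.45, against 14.31 to 14.49 and 14.57 to 14.68 on the other 11 arrays, and SAK measured 6.38 against at most 4.20.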
